A study of Mus musculus with 24 samples.

How the data were processed

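Gene expression was measured with 1 Affymetrix mouse array per sample in subcutaneous (inguinal) and visceral adipose tissue of 12 mice. Total RNA was labelled with the GeneChip WT PLUS kit. Per the labels, 6 mice carried the aP2-Tagln2 transgene (mice 60, 135 and 173, females, and 106, 130 and 158, males) and 6 were wild-type (mice 140, 169 and 170, females, and 159, 161 and 162, males). The groups were taken from the genotype, sex and tissue fields, which gave 8 groups of 3 samples, and all 24 columns of values were placed. The labels call the visceral depot epididymal in both sexes, and the source field of the subcutaneous samples speaks of visceral and inguinal depots at once. The tissue field was followed in every case, and no sample was moved or left out on the strength of its values.

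The deposited values are log2 intensities that the authors made with RMA, which corrects background, normalizes between arrays and summarises probes into probe sets. The submitters also name limma, with no version for either tool. The log base is not written in the file and was read from the range of the values, 1.678 to 13.08. The file holds 22142 probe sets, of which 19527 name 1 gene symbol and 2615 name none or several. The named ones cover 19494 genes, 33 of them with several probe sets, of which the one with the highest mean over all arrays was used. No read depth exists for arrays, and the number of arrays limits the precision. The genome build behind the probe sets is not named, so no coordinates are given.

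A gene was tested in a fit if it lay above the 40th percentile of its array in at least 3 arrays of the fit. Group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted by Benjamini and Hochberg over the genes of each comparison, with a threshold of 0.05. The 13 comparisons were genotype in each depot with the sexes averaged, genotype in each sex and depot, the genotype by sex interaction in each depot, the genotype by depot interaction, depot in each genotype, and sex in wild-type mice in each depot. Genotype and sex were compared in a fit of the 12 samples of a depot, depot in a fit of the 12 samples of a genotype, and the depot interaction in a fit of all 24. The level of Tagln2 was also compared by a two-sided exact permutation test of the group means.

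Lists of genes, 27 in number, were fixed before the data were examined, as were the comparisons, the filter and the rule for naming genes. They hold 483 genes, of which 445 were measured. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with the adjustment over the lists of a comparison, and again with a correlation estimated from the data and with fry. The rule names, for each comparison, up to 10 genes per direction with the largest change among those past the test whose groups do not overlap within a sex, with predicted genes left out. Where fewer than 3 pass, the genes of lowest p fill up to 5. Up to 4 members of lowest p are named from a list that is spoken of, and Tagln2, Tagln, Tagln3 and Fabp4 always. A list of 10 lymph node structure genes was written after the values of several of them had been seen.

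Each mouse gave both depots, so mouse numbers pair the samples as the same animal. The deviations of the pairs from their group means correlated between -0.259 and 0.196 over the 12 mice, and 5 of them exceeded 0.1. Fits with the mouse as a block were run as alternatives. The other alternatives were no filter and a stricter one, a second quantile normalization, centring each array on its median, limma's trend and robust options, array weights, all probe sets, a fold change of at least 1.5, no term for sex, and leaving out each mouse in turn. Chosen after the data were seen were fits without mice 158 and 159, whose subcutaneous arrays have a narrow range of values, list tests without those mice, without mouse 60 or without mouse 106, and fits with a lymphoid and a skeletal muscle score as covariates.

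The pipeline was tested on simulated data with the spread of these samples, with 50 genes changed at each fold. Noise was drawn for each gene on its own, so the variation that genes of real samples share was left out. In subcutaneous tissue with the sexes averaged it recovered 78% of genes changed 2-fold and 92% of those changed 4-fold. In subcutaneous tissue of females the shares were 30% and 92%, and for the subcutaneous interaction 8% and 64%. In visceral tissue with the sexes averaged they were 90% and 100%. The shares need not hold for the real samples. In visceral tissue 96% of genes changed 3-fold were recovered, while Tagln2, at 3.03-fold, had adjusted p = 0.996 by limma. Xist and Ddx3y were not analysed here, since no probe set is annotated with either symbol.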

Results

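Adipose tissue was profiled in 12 mice, 6 with an aP2-Tagln2 transgene and 6 wild-type, with 3 females and 3 males of each genotype. Tagln2 encodes transgelin-2, an actin-binding protein, and aP2 names the promoter of Fabp4, which is active in adipocytes. Each mouse gave a subcutaneous and a visceral sample, so the 24 arrays form 8 groups of 3. The values are RMA intensities on a log2 scale over 22142 probe sets. Array medians lay between 5.449 and 5.668. The standard deviation within an array ran from 1.46 in the subcutaneous sample of mouse 158 to 1.823 in the visceral sample of mouse 130. The subcutaneous sample of mouse 159 had the next narrowest spread, at 1.546. In the library labelled visceral of the aP2-Tagln2 female 60, the mesothelial genes Upk3b (4.39) and Wt1 (4.78) were near the subcutaneous level of wild-type females, and in its library labelled subcutaneous they stood at 7.59 and 5.59. Both libraries were kept as labelled. Background was not measured for each probe set, so where at least 3 of 6 or 2 of 3 arrays of the lower side lie under the level of the low-value filter, which ran from 4.94 to 5.31 over the arrays, differences are given on the log2 scale of the signal with no fold.

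The first question was whether the transgene raised Tagln2 in each depot. In subcutaneous tissue Tagln2 stood at 10.29 ± 0.50 (SD, n = 6) in aP2-Tagln2 mice and at 7.99 ± 0.43 (n = 6) in wild-type mice, a 4.93-fold difference. In visceral tissue the levels were 10.09 ± 0.84 (n = 6) and 8.49 ± 0.24 (n = 6), a 3.03-fold difference. In both depots the lowest aP2-Tagln2 sample (9.49 subcutaneous, 9.13 visceral) was above the highest wild-type sample (8.47 and 8.78). The exact permutation test gave p = 0.00216 in each depot, the smallest value 6 samples against 6 allow. By sex, the difference was 4.98-fold in females and 4.88-fold in males in subcutaneous tissue, and 3.95-fold and 2.32-fold in visceral tissue, each with an exact permutation p of 0.1, the smallest for 3 against 3. The interaction with sex was 0.03 (SE 0.52, adjusted p = 0.987) for Tagln2 in subcutaneous and 0.77 (SE 0.62, adjusted p = 1) in visceral tissue on the log2 scale. The visceral values of females lean on mouse 60, at 11.5 against 10.5 and 9.13 in the other aP2-Tagln2 females. Without mouse 60 the visceral log2 difference over both sexes was 1.32, against 1.6 with it.

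**Figure D1:**
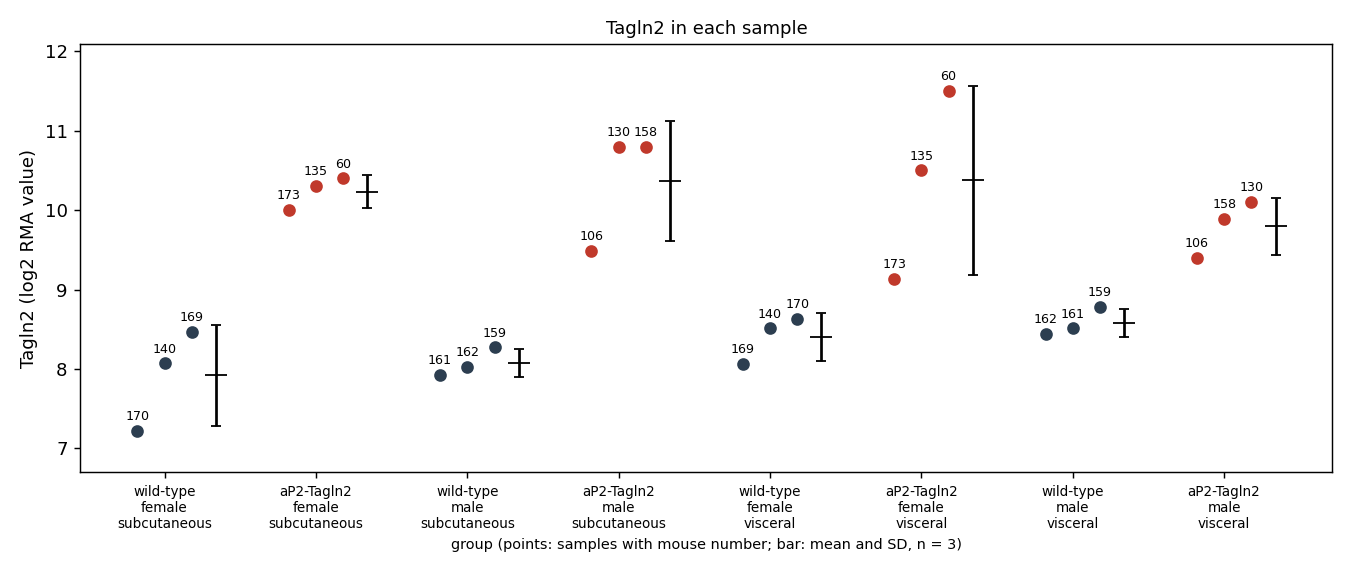
Tagln2 in each of the 24 samples on the log2 RMA scale, by genotype, sex and depot. Points are samples with their mouse number, bars the mean and SD of 3 samples, and the aP2-Tagln2 samples of each depot lie at or above 9.13 while the wild-type samples lie at or below 8.78.

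The next comparison asked what else differed in subcutaneous tissue between aP2-Tagln2 and wild-type mice, with the sexes averaged. Tagln2 itself was the 1 gene of 13101 that rose past the test (log2 difference 2.30, SE 0.26, adjusted p = 0.00969), and 0 genes fell. Its relatives Tagln (-0.23, SE 0.26) and Tagln3 (-0.07, SE 0.16) and the adipocyte fatty acid carrier Fabp4 (-0.11, SE 0.12) did not pass. Fabp4 stood at 12.4 to 12.7 in the samples, near the array maxima of 12.72 to 13.08, where a difference can go unmeasured. The sign for Tagln3 turned without mouse 130 (0.02) or 140 (0.00). Among genes of fatty acid synthesis, 0 of 17 members passed and all 17 had lower means in aP2-Tagln2 mice, with a median of -0.51. The elongase Elovl6 was at -1.56 (SE 0.52) and the fatty acid synthase gene Fasn at -0.91 (SE 0.41), both with adjusted p = 1. Of 23 genes of oxidative phosphorylation 0 passed and 23 had lower means (median -0.44), as did 18 of 19 genes of fatty acid oxidation (median -0.47), again with 0 past the test. At the preset correlation camera gave adjusted p = 1.3e-10, 1.8e-14 and 1.8e-14 for the 3 lists, and each had adjusted p = 0.34 with an estimated correlation. These differences were mostly those of males, with medians of -1.11 for fatty acid synthesis, -0.72 for oxidative phosphorylation and -0.91 for fatty acid oxidation, against -0.12 (10 of 17 lower), -0.09 (15 of 23 lower) and 0.10 (11 of 19 higher) in females. The interaction with sex had adjusted p = 0.60, 0.60 and 0.54 for the 3 lists with an estimated correlation. The adipocyte score of aP2-Tagln2 males was lower too, at 9.71 to 10.3 against 10.3 to 10.9 in wild-type males. A smaller share of adipocytes in these samples was thus not told apart from lower expression within adipocytes. Adipocyte genes had lower means in 18 of 20 cases (adjusted p = 4.4e-05) and T cell genes higher means in 15 of 15 (adjusted p = 0.00013), both with adjusted p = 0.41 with an estimated correlation. These too are the directions of males, since in females the adipocyte median was 0.21 (15 of 20 higher) and the T cell median -1.27 (15 of 15 lower). The female adipocyte value leans on mouse 60, whose depot markers are described above. Its adipocyte score was 11.2, against 9.68 and 10.6 in the other aP2-Tagln2 females and 10.2 in each wild-type female. The next genes by p were Cdcp3 at -1.18 (SE 0.18, adjusted p = 0.0953) and Cyp3a57, a cytochrome P450 gene, at -1.09 (SE 0.26, adjusted p = 1). By limma 250 genes had an unadjusted p under 0.05, where 655 would come by chance. The call for Tagln2 was lost without mouse 161 (adjusted p = 0.0589, 0 genes), without mouse 162 (adjusted p = 0.0581, 0 genes) and without mice 158 and 159 together (adjusted p = 0.161, 0 genes). Its log2 difference changed little in these fits, at 2.26, 2.29 and 2.24.

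In visceral tissue the same comparison gave 0 genes of 12706 by limma, with 510 at an unadjusted p under 0.05 where 635 would come by chance. Tagln2 had the largest difference among the named genes (1.60, SE 0.31, adjusted p = 0.996), beside the exact test above. Gnb4, a G protein beta subunit, was at 0.56 (SE 0.12) and Rbp7, a retinol-binding protein, at -0.52 (SE 0.11), both with adjusted p = 0.996. Of 17 genes of fatty acid synthesis 0 passed and 15 had lower means, with a median of -0.39, Elovl6 at -1.33 (SE 0.46) and Fasn at -0.66 (SE 0.27). Camera gave adjusted p = 4.3e-07 for that list and adjusted p = 0.64 with an estimated correlation. Without mouse 173 the count was 2 genes, 1 higher and 1 lower.

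In females, subcutaneous Cdcp3 fell to 4.95 ± 0.29 (n = 3) in aP2-Tagln2 mice from 7.35 ± 0.38 (n = 3) in wild-type mice, a log2 difference of -2.40 (SE 0.25, adjusted p = 0.00391). It was the 1 gene past the test, with no overlap between the groups, and its levels in males were 4.86 ± 0.30 and 4.83 ± 0.19 (n = 3 each). In mouse 60, whose depot markers are described above, Cdcp3 was 4.70 in the library labelled subcutaneous and 6.56 in the one labelled visceral, so the size of the difference depends on those labels. In 2 of the 3 aP2-Tagln2 samples Cdcp3 lies under the filter level. Cyp3a57 was lower at -2.16 (SE 0.37, adjusted p = 0.246) and Mmd2 at -1.81 (adjusted p = 1) in aP2-Tagln2 females. Cyp3a57 also lay under the filter level in 2 of the 3, and the size of its difference too depends on mouse 60, where it was 3.17 in the library labelled subcutaneous and 6.22 in the one labelled visceral. Of the T cell genes 0 of 15 passed and all 15 had lower means in aP2-Tagln2 females (median -1.27, Cd3g at -2.14, SE 0.94), and of the B cell genes 0 of 15 passed with 15 lower means (median -1.75, Pax5 at -1.85, SE 0.66). Camera gave adjusted p = 5.7e-14 and 7.1e-20 for these lists, and adjusted p = 0.31 and 0.23 with an estimated correlation. The mean of the T and B cell scores was 4.53 in mouse 60, 4.71 in mouse 173 and 6.20 in mouse 135, the last within the wild-type females (6.12 to 6.87). By limma 244 genes had an unadjusted p under 0.05, and without mouse 106, a male that enters through the shared spread, the count was 2. The Cdcp3 call held in all 23 alternatives run. The adjusted p was 4.59e-05 with array weights, which had not converged, and 0.00288 to 0.0427 in the others.

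**Figure D2:**
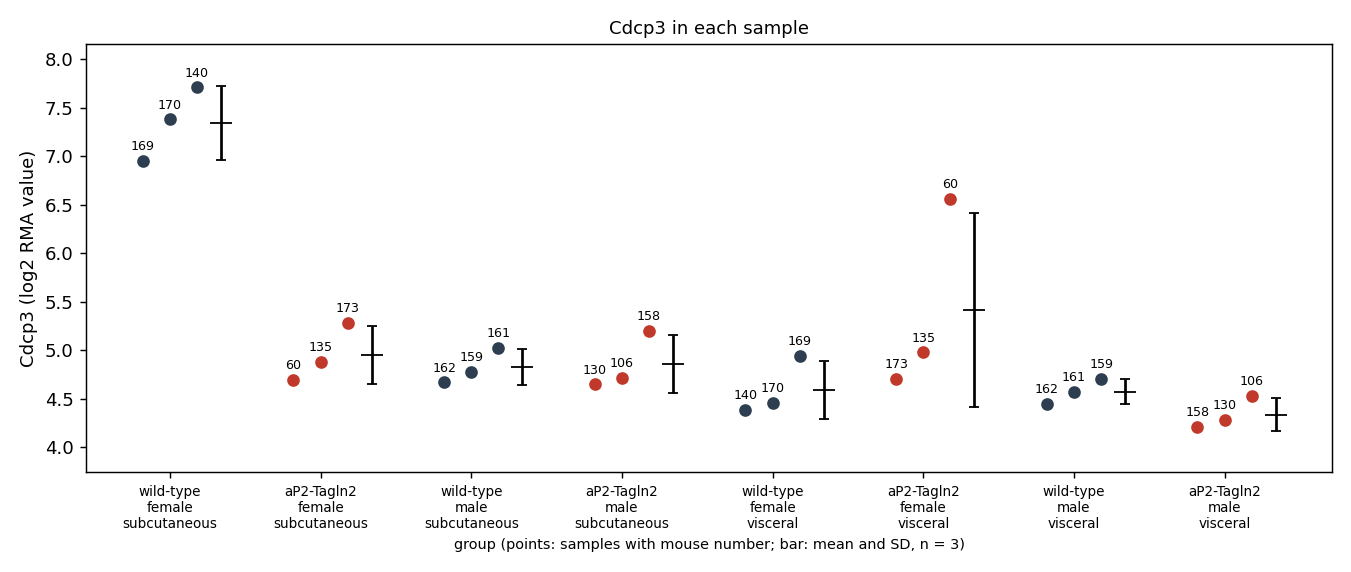
Cdcp3 in each of the 24 samples on the log2 RMA scale, by genotype, sex and depot. Points are samples with their mouse number and bars the mean and SD of 3 samples; subcutaneous wild-type females average 7.35 and subcutaneous aP2-Tagln2 females 4.95.

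In subcutaneous tissue of males 0 of 13101 genes passed by limma, with 1700 at an unadjusted p under 0.05. The T cell receptor component Cd3e was higher at 2.31 (SE 0.58, adjusted p = 0.277) and the B cell receptor component Cd79a higher at 2.92 (SE 0.89, adjusted p = 0.282) in aP2-Tagln2 males. All 15 T cell genes (median 2.31) and all 15 B cell genes (median 2.09) had higher means, and 15 of each passed when adjusted over the list alone. Smooth muscle genes had lower means in all 15 cases (median -0.68), 7 of them past the test adjusted over the list alone, with Acta2 at -1.60 (SE 0.33) and Myl9 at -1.38 (SE 0.27). Of 19 genes of fatty acid oxidation 17 passed with lower means when adjusted over the list alone (median -0.91), among them Pdk4, an inhibitor of glucose oxidation, at -2.14 (SE 0.41) and the carnitine carrier Slc25a20 at -1.54 (SE 0.40). With an estimated correlation the adjusted p was 0.34 for the T cell, B cell and oxidation lists and 0.32 for smooth muscle. Lists of cell types and matrix had lower means in the same comparison with 0 members past either test, among them adipocyte genes in 19 of 20 cases (median -0.65, camera adjusted p = 4.1e-07), endothelial genes in 15 of 15 (median -0.53, adjusted p = 3.7e-06) and extracellular matrix genes in 23 of 27 (median -0.49, adjusted p = 4.1e-05), with adjusted p = 0.36, 0.35 and 0.35 with an estimated correlation. The mean of the T and B cell scores was 7.53 in mouse 106, 7.72 in mouse 130 and 4.95 in mouse 158, against 4.51 to 4.84 in wild-type males. The adipocyte score was 9.86, 9.71 and 10.3 in these mice, against 10.3 to 10.9 in wild-type males. The count was 1419 genes (1229 higher, 190 lower) without mouse 158, 1 without mouse 106, 997 without mice 158 and 159, and 290 (200 higher, 90 lower) in a fit of all 24 arrays with the mouse as a random block.

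The title of the series names dependence on sex, which the interaction tests directly as the genotype difference in females minus that in males. In subcutaneous tissue 0 of 13101 genes passed by limma, with 1613 at an unadjusted p under 0.05, and the lowest adjusted p was that of Cdcp3 (-2.42, SE 0.35, adjusted p = 0.151). Cd3e was at -3.61 (SE 0.83) and Cd79a at -5.31 (SE 1.26), both with adjusted p = 0.218, and all 15 T cell genes (median -3.30) and all 15 B cell genes (median -3.79) passed when adjusted over the list alone. The smooth muscle genes had the opposite sign in 15 of 15 cases (median 1.07, 8 past the test adjusted over the list alone), with Acta2 at 2.05 (SE 0.47) and Myl9 at 1.82 (SE 0.38). With an estimated correlation the adjusted p was 0.26 for T cells, 0.26 for B cells and 0.22 for smooth muscle. The count became 1247 (158 higher, 1089 lower) without mouse 158, 706 (483 higher, 223 lower) without mouse 135, 976 without mice 158 and 159, and 398 (103 higher, 295 lower) in the fit of all 24 arrays with the mouse as a random block.

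**Figure D3:**
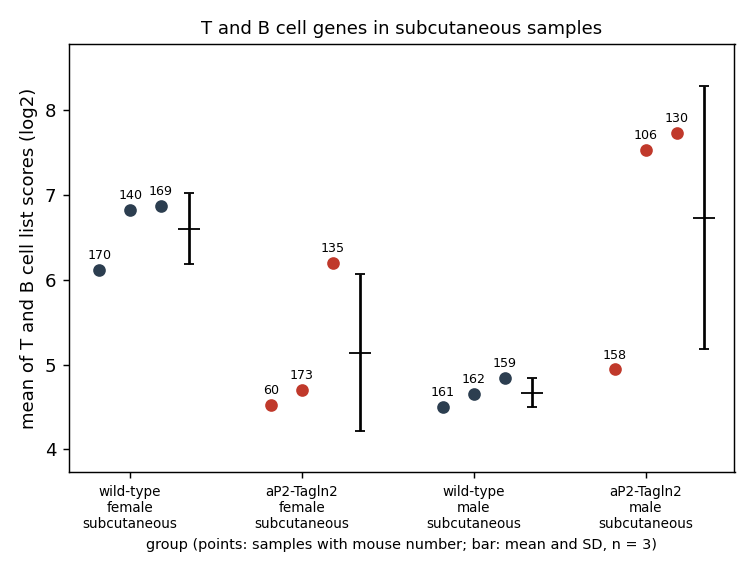
Mean of the T cell and B cell list scores in the 12 subcutaneous samples on the log2 scale. Points are samples with their mouse number and bars the mean and SD of 3 samples; the wild-type males lie between 4.51 and 4.84, and the aP2-Tagln2 males at 4.95, 7.53 and 7.72.

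In visceral tissue of females 0 of 12706 genes passed by limma, with 408 at an unadjusted p under 0.05. Of 12 mesothelial genes 0 passed and 9 had lower means in aP2-Tagln2 females (median -0.60), with Upk3b at -1.95 (SE 0.95) and Nkain4 at -1.13 (SE 0.52). Camera gave adjusted p = 0.0064 and adjusted p = 0.85 with an estimated correlation. Much of this comes from mouse 60, where Upk3b was 4.39 against 9.27 and 8.91 in the other aP2-Tagln2 females, and without it the difference for Upk3b was -0.39 and the median of the list -0.26. The count was 2 genes without mouse 173.

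In visceral tissue of males 0 of 12706 genes passed by limma, with 436 at an unadjusted p under 0.05. Skeletal muscle genes had lower means in 7 of 9 cases in aP2-Tagln2 males (median -0.25), 3 of them past the test adjusted over the list alone, and the list's adjusted p was 0.043 with an estimated correlation. The signal is low. The mean of all 15 members, tested or not, was 5.03 to 5.14 in aP2-Tagln2 and 5.34 to 5.51 in wild-type males. The low-value filter ran from 4.94 to 5.31 over the arrays. Acta1, skeletal actin, was at -1.15 (SE 0.37), Ckm, muscle creatine kinase, at -0.64 (SE 0.18) and Tnnc2, a troponin, at -0.72 (SE 0.15), each with adjusted p = 1 over all genes. Sult1e1, which sulfates oestrogens, was 2.86-fold higher and Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, 1.76-fold higher, both with adjusted p = 0.965. In the visceral interaction with sex 0 genes passed, 322 had an unadjusted p under 0.05, and skeletal muscle again gave adjusted p = 0.02 with an estimated correlation (median 0.37, 8 of 9 members positive, Acta1 at 2.11, SE 0.53). Without mouse 158 the count in males was 1 gene.

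Whether the genotype difference itself differed between depots was tested over all 24 samples. By limma 0 of 13688 genes passed, and 183 had an unadjusted p under 0.05 where 684 would come by chance. Cdcp3 came nearest by p (1.48, SE 0.33, adjusted p = 1), and Tagln2 was at -0.70 (SE 0.43, adjusted p = 1). All 19 genes of fatty acid oxidation were positive, with a median of 0.34 (camera adjusted p = 4.8e-09) and adjusted p = 0.56 with an estimated correlation.

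Depot was compared within wild-type mice, with the sexes averaged, as the baseline of the tissue. Mesothelial genes, which mark the lining of visceral fat, rose in visceral tissue in 9 of 12 cases and fell in 2, with Upk3b at 4.45 (SE 0.23, adjusted p = 3.22e-07), Wt1 at 1.79 (adjusted p = 6e-07) and Msln at 1.63 (adjusted p = 1.14e-05) on the log2 scale. Of 15 smooth muscle genes 11 rose and 0 fell, with Actg2 6.90-fold higher (adjusted p = 0.00717). Of 13 genes of the depot patterning list 5 rose and 4 fell, with no shared direction (camera adjusted p = 0.80), and Tcf21 was at 1.78, Hoxa5 at 0.91 and Tbx15 at -1.39. Among adipocyte genes 10 of 20 rose, including Mest at 6.18-fold and Dgat2, which makes triglyceride, at 1.51-fold, and of 15 thermogenic genes 6 fell and 1 rose, with Otop1 at -1.56. Agt, the angiotensin precursor, was 6.52-fold higher.

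Some of these depot differences were carried by 1 sex, though the difference between the sexes was not tested. Lymphocyte genes fell in 13 of 14 cases for T cells and 12 of 13 for B cells, with medians by sex of -1.88 and -2.11 in females against -0.11 and -0.01 in males, and Themis at -2.91 in females and -0.26 in males. Glycam1, a gene of lymph node vessels, passed as lower (-3.29, adjusted p = 2.18e-06) and was likewise a difference of females, at 8.98 to 10.6 in their subcutaneous and 3.29 to 3.84 in their visceral samples against 3.70 to 4.03 and 3.51 to 3.79 in males. Of other lymph node genes Ccl19 passed (-0.66, adjusted p = 0.0294) and Ccl21a (0.19) and Cxcl13 (-0.996) did not, so lymph node tissue taken with the pads of these females is open as a source. Of 14 mammary epithelial genes 7 fell, with a median of -1.41 in females and -0.17 in males, and the milk casein Csn3 was at -5.54 and -1.14. Mup9, Mup19, Mup22 and Mup2 fell by 0.887 to 1.09 in females and 4.82 to 5.63 in males, and these paralogs are so alike that their probe sets are not independent measures. Hoxc10 passed as lower (-0.79, adjusted p = 0.000943) although it was 0.42 higher in visceral tissue of females and lower in males (-2.00).

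In total 2836 of 12944 genes passed in wild-type mice, 1989 higher and 847 lower in visceral tissue, and 1285 of them differed at least 1.5-fold. The direction of the means was the same in both sexes for 2643 of them and opposite for 193, and for 1514 the 2 sexes also agreed within 2 times. Selection on the average of the sexes itself favours a shared direction. With an estimated correlation the lowest adjusted p of any list was 0.07, for the T cell genes, against 7.5e-16 at the preset correlation. The count was 886 without mouse 140, 1291 without mouse 159, 1448 without mouse 170 and 1862 without mouse 162.

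**Figure D4:**
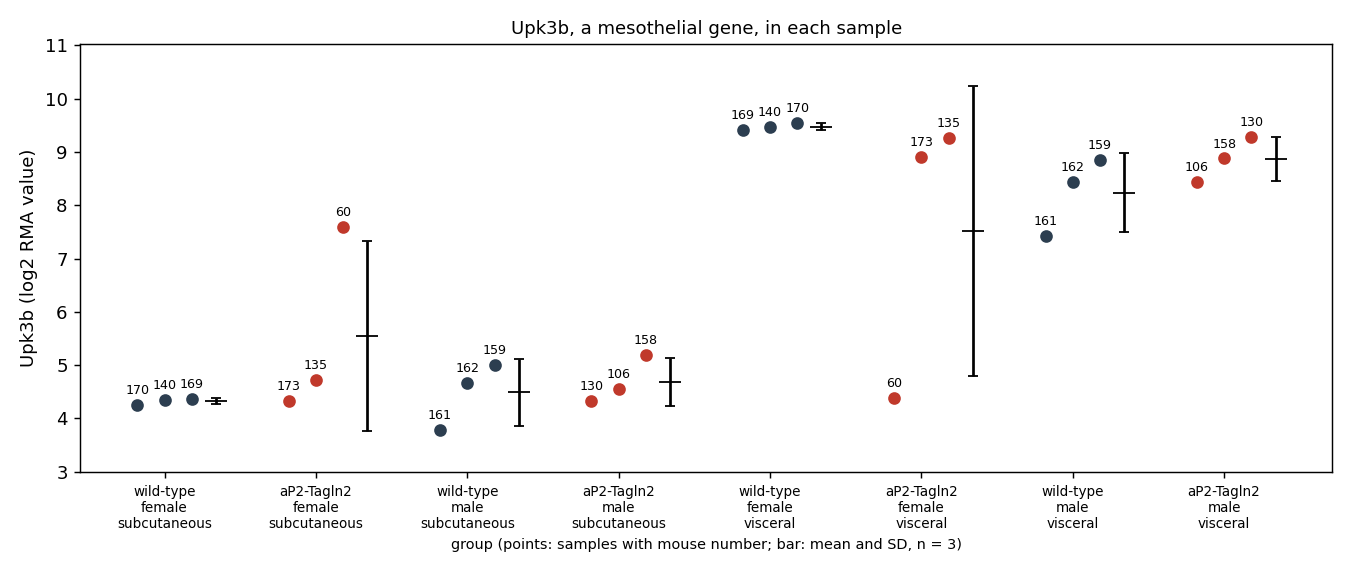
Upk3b in each of the 24 samples on the log2 RMA scale, by genotype, sex and depot. Points are samples with their mouse number and bars the mean and SD of 3 samples; mouse 60 stands at 4.39 in its library labelled visceral and at 7.59 in its library labelled subcutaneous.

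The same comparison in aP2-Tagln2 mice gave 143 of 13095 genes, 125 higher and 18 lower in visceral tissue, with the same direction of the means in both sexes for 140 of them but a size within 2 times for 26. Sult1e1 passed with the lowest p (log2 difference 1.76, SE 0.15, adjusted p = 0.000524), an average of -0.02 in females and 3.54 in males whose difference between the sexes was not tested. The mesothelial genes Nkain4 and Msln rose by 1.94 (adjusted p = 0.0457) and 1.41 (adjusted p = 0.0492), and the decoy receptor Il1r2 fell, at -1.50 (adjusted p = 0.0457). Podn, Pdzrn3 and Kctd10 were 2.06-fold to 2.28-fold higher (adjusted p = 0.0457). Of 12 mesothelial genes 3 passed over all genes, and 9 with higher means when adjusted over the list alone. Among the 12712 genes tested in both genotypes, 110 of the 124 higher calls in aP2-Tagln2 mice were shared with wild-type mice, where 19.3 would be shared if independent, and 10 of the 15 lower calls, where 0.944 would be. The count was 1705 without mouse 60, 439 without mouse 158, 0 without mouse 106, and 1 without mouse 130, 135 or 173 in turn. With the mouse as a fixed block it was 0, and as a random block 1, as it was with no filter or with centred arrays, and 3 after a second quantile normalization. The call for Sult1e1 held in 15 of 16 alternatives, those for Nkain4, Podn, Pdzrn3 and Kctd10 in 8 of 17, that for Msln in 7 of 17 and that for Il1r2 in 7 of 16.

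Sex was compared in wild-type mice, to set the baseline and to check the labels. In subcutaneous tissue the Y-linked genes Eif2s3y (adjusted p = 2.06e-06) and Uty (adjusted p = 8e-04) separated the sexes. Eif2s3y stood at 2.81 to 3.29 in females and 7.85 to 8.70 in males, and Uty at 2.24 to 2.42 and 5.96 to 6.65. Females carry no Y chromosome, so their values are background and no fold is given. Cdcp3 (log2 difference 2.52, adjusted p = 8e-04), Spon1 (2.73, adjusted p = 8e-04) and Cyp3a57 (3.04, adjusted p = 0.00179) were higher in females, while the complement gene C7 was 4.08-fold lower (adjusted p = 8e-04). The progesterone receptor gene Pgr (log2 difference 2.89, adjusted p = 0.04) and the epithelial keratin Krt19 (log2 difference 4.60, adjusted p = 0.0367) were also higher in females, but kept their calls in 13 and 12 of 23 alternatives, where the 6 genes above kept theirs in all 23. Mammary epithelial genes had higher means in females in 13 of 14 cases, 11 past the test adjusted over the list alone (adjusted p = 0.46 with an estimated correlation), and extracellular matrix genes lower means in 25 of 27 cases, 11 adjusted over the list alone (adjusted p = 0.25 with an estimated correlation). All 15 T cell genes (median 1.74, 13 past the test adjusted over the list alone) and all 15 B cell genes (median 2.10, 14 past) had higher means in females, both with adjusted p = 0.46 with an estimated correlation. Of 6 lymph node genes the 4 whose values had been seen when their list was written had higher means in females and the 2 others lower ones, with Glycam1 at 6.17 (adjusted p = 0.0915, 8.98 to 10.6 in females and 3.70 to 4.03 in males) and Ccl21a at 1.76 (adjusted p = 0.244, 8.05 to 9.26 and 6.56 to 7.89), neither past the test, so lymph node tissue is open here as well. With lymphoid and skeletal muscle scores as covariates 16 genes passed, 14 of them among the 57. The 57 genes past the test, 18 higher and 39 lower, became 982 without mouse 158, 185 without mouse 60, 31 without 106, 28 without 161, 24 without 170, 22 without 162, 20 without 159 and 18 without 140 or 169. The count was 587 in the fit of all 24 arrays with the mouse as a random block.

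In visceral tissue Ucp1, the uncoupling protein of thermogenic fat, was higher in females (log2 difference 4.11, SE 0.42, adjusted p = 0.000802), the oxytocin receptor gene Oxtr 6.32-fold higher (adjusted p = 0.0324) and Hoxc10 higher at 2.26 (adjusted p = 2.84e-05). Sult1e1 was lower in females (log2 difference -3.55, adjusted p = 0.000106) and Hoxc8 2.16-fold lower (adjusted p = 0.014). The calls for Oxtr and Hoxc8 held in 13 and 17 of 22 alternatives and that for Ucp1 in 21. Mup22 and Mup19 were 33.2-fold and 44.2-fold higher in females and Mup9 was higher at 5.63, with the same limit as above for near-identical paralogs. The labels name an epididymal depot, which females lack, so the visceral samples of the sexes need not come from the same site. In total 40 of 12706 genes passed, 17 higher and 23 lower, with Uty lowest in adjusted p (1.01e-09). The count was 79 without mouse 60, 24 without 130, 22 without 159, 20 without 170, 15 without 162, 13 without 161 or 169 and 11 without 140, and 22 in the fit of all 24 arrays with the mouse as a random block. Of the genes called, 1 higher (Oxtr) and 12 lower were shared between depots. The lower ones were the Y-linked Uty and Eif2s3y, the inflammation marker Lrg1, and otherwise predicted genes with names from Gm20736 to Gm20867.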

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

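Apart from the counts over other splits of the samples, the tests that weigh explanations in this part were chosen after the result was seen. Sets of 6 samples (a genotype in a depot) were searched on each of several measures for a sample far from the rest, by its gap to the nearest sample as a share of the set's range. Of 108 pairs of a set and a measure 8 held one, where chance gives about 1 in 20. The pairs share samples and are not independent, and 8 of 108 is not far from that share, so a flag alone does not exclude chance. In visceral aP2-Tagln2 samples, mouse 60 stood apart for mesothelial genes (0.664, lowest), mammary epithelial genes (0.906, highest) and stromal progenitor genes (0.634). Mouse 173 stood apart there for T cell genes (0.717) and interferon genes (0.626), and mouse 135 for smooth muscle genes (0.803). Mouse 106 stood apart in subcutaneous aP2-Tagln2 samples for immediate early genes (0.854), and mouse 169 in visceral wild-type samples for the standard deviation of its array (0.777).

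The library of mouse 60 labelled visceral held Upk3b at 4.39, and its library labelled subcutaneous at 7.59. The mesothelial score was 5.91 and 5.72, and the visceral sample of the wild-type male 161 was at 5.86. That list also holds the keratin Krt19, at 9.15 in the library labelled visceral and 4.52 in the other. Wild-type females had Krt19 at 8.09 to 8.8 in subcutaneous and 5.53 to 6.27 in visceral samples. In the mean Krt19 therefore offsets Upk3b, and the score cannot decide. A depot index over 349 genes set the wild-type female subcutaneous mean at 0 and the visceral mean at 1. Exchanged depot labels are a candidate explanation: the library labelled subcutaneous had an index of 0.868, which lies on the visceral side. The library labelled visceral, at 0.325, misses the bound set for it. Subcutaneous samples of other mice miss that bound too, at 0.267 in mouse 173 and 0.504 to 0.626 in wild-type males, so the bound cannot decide. The array closest to this library was the subcutaneous one of mouse 173 (correlation 0.9755). The library of mouse 60 labelled subcutaneous was closest to the visceral one of mouse 170 (0.9755). An effect of the transgene on depot markers is argued against by the other 5 visceral aP2-Tagln2 samples, whose lowest index was 0.906. Exchanging the depots of mouse 60 alone called 2851 genes between depots in aP2-Tagln2 mice against 143 as labelled, which points to a structure of the samples.

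Among subcutaneous samples several lists differed in their genotype effect between the sexes at the preset correlation, and none of them with an estimated one. The medians, females minus males, were -3.30 for T cell genes, -3.79 for B cell genes, -0.36 for NK, mast cell and neutrophil genes (-0.00191 without mouse 60), -0.62 for cell cycle genes, 0.90 for adipocyte genes, 0.79 for fatty acid synthesis, 0.84 for fatty acid oxidation, 1.12 for thermogenic genes, 0.59 for oxidative phosphorylation, 1.07 for smooth muscle, 0.66 for extracellular matrix, 0.87 for endothelial and 1.7 for skeletal muscle genes. The lymphocyte part may come from lymph node tissue taken with some inguinal pads. Of 6 tested lymph node structure genes, the 4 whose values had been seen when the list was written had a median of -3.94. The 2 others (Tnfsf11 and Fcamr) had -0.413, with -2.83 over all 6. The unseen genes cannot decide it, since they ran from 4.1 to 5.88 in these samples, near the level of the low-value filter. Glycam1, a seen gene, was 5.86 to 10.6 in subcutaneous samples with lymphoid scores of at least 6.12 and 3.49 to 4.24 in the others. A genotype effect that differs by sex stays open as well, since 2 of 3 aP2-Tagln2 males had a lymphoid score more than 1 above the highest wild-type male and the remaining one did not.

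Cdcp3 was lower in subcutaneous samples of aP2-Tagln2 females. The libraries of mouse 60 are argued against as the cause by an adjusted p of 0.0316 without that mouse (0.00288 to 0.0427 over the alternatives other than array weights). That leaves open the size of the difference if the depot labels of that mouse were exchanged, since its library labelled visceral had Cdcp3 at 6.56, and no fit with exchanged labels was made for it. Less mammary epithelium as a whole is argued against by the mammary list, whose median without mouse 60 was 0.154 where Cdcp3 was at -2.27, although with all mice 13 of 14 members were lower (median -0.40, camera adjusted p = 0.0012). A list median cannot speak to a part of that epithelium. In mice 135 and 173 Pgr (5.93 and 7.16) and Cyp3a57 (4.59 and 5.04) also lay under the wild-type females (7.62 to 7.97 and 6.27 to 6.7). Krt19 did not, at 8.22 and 9.39 against 8.09 to 8.8. Unequal lymphoid and skeletal muscle tissue is argued against by an adjusted p of 0.00541 with both scores as covariates. An effect of the transgene in females, or on the female level of Cdcp3, may remain as a hypothesis, found and tested on the same 12 samples.

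In visceral samples the lists that differed by sex at the preset correlation had medians of 0.13 for fatty acid oxidation, 0.24 for thermogenic genes (0.235), 0.10 for oxidative phosphorylation (0.099), -0.29 for insulin signalling, -0.51 for macrophage, -0.88 for mesothelial, 0.50 for mammary epithelial (-0.000236 without mouse 60) and 0.37 for skeletal muscle genes, and the last held with an estimated correlation (adjusted p = 0.02). The visceral calls for fatty acid oxidation, thermogenic genes and oxidative phosphorylation ended without mouse 60 (adjusted p = 0.45, 0.11 and 0.46) and without mouse 106 (0.16, 0.11 and 0.35). Their medians were -0.00309, 0.171 and 0.0404 without mouse 60. Without mouse 106 the first and second stayed near their size (0.113 and 0.245) and the third was 0.0192. Between depots the genotype effect differed, visceral minus subcutaneous, by medians of 0.17 for adipocyte genes (0.165), 0.34 for fatty acid oxidation, 0.24 for thermogenic genes, 0.25 for oxidative phosphorylation (0.248), 0.13 for insulin signalling, 0.20 for extracellular matrix (0.198), -0.17 for macrophage, -0.31 for T cell, -0.20 for interferon, 0.25 for endothelial (0.253), 0.45 for mammary epithelial (-0.0909 without mouse 60) and -0.19 for cell cycle genes, none with an estimated correlation. The macrophage call ended without mouse 60 (adjusted p = 0.17) and the T cell call without mouse 106 (adjusted p = 0.43). Probe sets without a single gene name were left out of the comparisons. In fits of such probe sets alone 577 of 1650 passed between depots in wild-type mice, 173 of 1725 between the sexes in subcutaneous and 104 of 1536 in visceral tissue.

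Other splits of the same samples were fitted in the same way, 100 drawn where more exist. For depot in wild-type mice 1 of 100 splits, the real one, gave as many genes as 2836 (highest other 975), and 1 of the 32 splits that part every mouse. Both shares are under 0.05 and the smallest that these splits allow, so chance is unlikely. For depot in aP2-Tagln2 mice 2 of 100 splits gave at least 143 (highest other 1292), but those splits do not keep the mice paired. Of the 32 that part every mouse 3 did (highest other 2851). The split with 2851 exchanged mouse 60 alone, whose depot labels are in question above. These splits therefore do not exclude chance and cannot decide on it. Chance was not excluded for the count of genes between genotypes in subcutaneous tissue (1 gene, 6 of 100 splits, highest other 366). The count does not ask which gene passed. That gene was Tagln2, for which the exact permutation test gave p = 0.00216. A real count of 0 is met by every split (100 of 100), so the splits say nothing about chance there. This holds for genotype in visceral tissue (highest other 2), the interaction with sex in subcutaneous (highest other 831) and visceral tissue (highest other 23) and the interaction with depot (highest other 571). Splits with 366, 831 and 571 genes against 1 or 0 point to a structure of the samples other than genotype. Comparisons of 3 samples with 3 have 10 splits, too few for a share under 0.05. Their real counts and highest others were 1 and 37 for subcutaneous females (2 splits at least as high), 0 and 0 for subcutaneous males (10), 0 and 2 for visceral females (10), 0 and 4 for visceral males (10), 57 and 1 for sex in subcutaneous tissue (1) and 40 and 0 for sex in visceral tissue (1).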

How the results depend on the processing

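Fits without mice 158 and 159, with lymphoid and skeletal muscle scores as covariates, and list tests without mouse 60, without mouse 106 or without mice 158 and 159 were chosen after the data were seen. A stricter filter, trend and robust options and no term for sex moved no count beyond 1.5 times. With 3 arrays per group, the number of arrays limits what can be called. Signal over background was not measured here. Where no reason is given below, the cause was not tested. Array weights gave 580 genes for genotype in subcutaneous tissue (1 as reported), 3120 in females (1), 4382 in males (0), 5623 for the interaction with sex (0), 2976 for sex in subcutaneous tissue (57) and 1929 for depot in aP2-Tagln2 mice (143). The weights had not converged in any of these, and ran from 0.139 for mouse 158 to 14.9 for mouse 173 in the subcutaneous fit, so these counts are not read as results. A fit of all 24 arrays with the mouse as a random block gave 290 for subcutaneous males, 398 for the subcutaneous interaction with sex, 587 for sex in subcutaneous and 22 for sex in visceral tissue (40). For depot in aP2-Tagln2 mice the mouse gave 0 as a fixed and 1 as a random block, with a consensus correlation of -0.0327, while the block left the counts for depot in wild-type mice (2346 and 2734) and for the depot interaction (0 and 0) within 1.5 times. The fixed block ended the call of 23 of 70 named depot genes and the random block that of 22, both over the same arrays. The fit of all 24 arrays ended 8 and added 19 calls among 107 named results, but it changes the arrays as well as the block (consensus correlation -0.0281), so these moves are not put down to the block. The same comparison gave 1 with no filter, 3 with a second quantile normalization and 1 with centred arrays. A fold change of at least 1.5 left 1285 of the depot genes in wild-type mice. Testing all probe sets gave 268 and 148 genes for sex in subcutaneous and visceral tissue, where unnamed probe sets are added. Without mice 158 and 159 the counts were 0 for genotype in subcutaneous tissue, 997 in males, 976 for its interaction with sex, 1291 for depot in wild-type and 439 in aP2-Tagln2 mice, and 254 and 16 for sex in subcutaneous and visceral tissue. With both scores as covariates sex in subcutaneous tissue gave 16. Leaving out each mouse in turn gave, for genotype, 0 to 1 genes in subcutaneous tissue, 0 to 2 in visceral, 1 to 2 in subcutaneous females, 0 to 1419 in subcutaneous males, 0 to 2 in visceral females and 0 to 1 in visceral males. It gave 0 to 1247 for the interaction with sex in subcutaneous tissue, 0 to 0 in visceral tissue and 0 to 0 for the depot interaction, 886 to 2772 for depot in wild-type and 0 to 1705 in aP2-Tagln2 mice, and 18 to 982 and 11 to 79 for sex in subcutaneous and visceral tissue. Some values changed sign. Tagln3 in subcutaneous tissue was 0.0983 with array weights, and ran from -0.136 without mouse 106 to 0.02 without mouse 130, with 0.00207 without mouse 140. Tagln2 in the subcutaneous interaction with sex was -0.00931 after quantile normalization, -0.262 with covariates, and -0.0668, -0.407, -0.0715 and -0.322 without mouse 60, 106, 159 and 170, up to 0.303 without mouse 169. Tagln2 for sex in subcutaneous tissue was 0.0903 with array weights, 0.101 with covariates and 0.195 without mouse 170, down to -0.43 without mouse 169. For depot in aP2-Tagln2 mice it ran from -0.436 without mouse 60 to 0.0477 without mouse 173. Without mouse 60 the mammary epithelial list changed sign in subcutaneous females (adjusted p = 0.054), in the visceral interaction with sex (0.91) and in the depot interaction (0.28). Without mouse 106 camera's direction for the immediate early list turned in males of both depots. Its median stayed positive in subcutaneous tissue (0.0418, from 0.81, adjusted p = 0.48) and turned negative in visceral tissue (-0.08, from 0.263, adjusted p = 0.68). Of 138 list calls at the preset correlation 3 held with an estimated one and 21 with fry. The log2 difference of Tagln2 between genotypes stayed positive in every alternative run on its level, from 2.15 to 2.46 in subcutaneous and from 1.32 to 1.79 in visceral tissue.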

Other observations

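The list tests without mouse 60 or 106 were chosen after the result was seen. In subcutaneous tissue of aP2-Tagln2 mice interferon response genes had higher means in 17 of 17 cases (median 0.30, adjusted p = 1.9e-09, and 0.34 with an estimated correlation), and macrophage genes in 14 of 17 (median 0.26, adjusted p = 5.2e-05, and 0.34). Both scores were high in males 106 (6.27 and 7.39) and 130 (6.67 and 7.63), whose lymphoid scores were also high. Male 158 (5.63 and 6.81) lay within wild-type males (5.52 to 5.86 and 6.53 to 7.22). In females the genotypes overlapped, for interferon at 5.97 to 6.39 against 5.9 to 6.28 in wild-type mice, and for macrophages at 6.51 to 7.04 against 6.32 to 7.01. Immediate early genes, which respond to handling and stress, had higher means in 14 of 14 cases in both depots (medians 0.39 and 0.25), with adjusted p = 0.37 and 0.64 at an estimated correlation. In subcutaneous tissue this rests on mouse 106, whose score was 9.02 against 6.41 and 6.29 in the other aP2-Tagln2 males and 6.48 to 6.67 in wild-type males, and without it the median was -0.0394 (adjusted p = 0.82). Mouse 106 also had the highest visceral score, 7.47. In visceral tissue smooth muscle genes had lower means in 14 of 15 cases (median -0.31, adjusted p = 0.0039, and 0.70 with an estimated correlation), a call that ended without mouse 60 (median -0.14, adjusted p = 0.13).

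In wild-type mice the matrix gene Postn (log2 difference -1.20), the matrix protease Mmp3 (-2.51) and the skeletal muscle myosin Myh2 (-1.49) were lower in visceral than in subcutaneous tissue, all past the test. All 15 skeletal muscle genes had lower means, whether past the test or not (median -1.49, adjusted p = 0.49 with an estimated correlation). The subcutaneous score was uneven, at 9.44 in mouse 170 and 8.17 in mouse 159 against 5.04 to 6.42 in the other wild-type mice.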
